A study of Mus musculus with 8 samples.

How the data were processed

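Total RNA of 8 mouse tumours was extracted with Trizol, labelled with biotin and measured on Affymetrix whole-transcript mouse arrays, 1 array per tumour. The deposited values are log2 expression levels per probe set. The authors made them with RMA (background correction, quantile normalization between arrays and a summary per probe set) and Partek 6.5, per the submitters' processing notes, which name both tools without saying which step each did. The log2 scale was read from the values, which run from 2.07 to 13.61 over the 8 arrays and are not centred per probe set. Other options, filters and the annotation behind the values are not given in the sources used here. Arrays carry no count of molecules, and their number limits the precision.

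The table holds 41345 probe sets. The platform annotation names 25335 of them, 23521 with 1 gene symbol and 1814 with several, and 16010 are unnamed here. No gene was named from a probe set with several symbols. Each gene was read from its probe set with the highest mean over the 8 arrays, which gave 22180 genes. Chromosomes were taken by Entrez identifier from a gene table of the GRCm38.p6 assembly, which held 21994 of the genes and lacked 186. The build behind the probe sets is not given in the sources used here, so no coordinates are printed. Of 32 genes fixed in advance, 27 had a value, and the others, Trp53 among them, are not analysed here. The 28 gene lists held 402 genes, of which 360 had a value.

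The labels give 1 group, so no groups were compared. Detection was tested with limma 3.58.1 in R 4.3.3 (a linear model with moderated variance, trend and robust prior) as the mean over the tumours of a gene's level minus the background of the same array. The background was the 95th percentile of 1437 probe sets of olfactory, vomeronasal and bitter taste receptor genes. A gene above 0 with a Benjamini-Hochberg adjusted p under 0.05 was called detected. The share of detected genes in a list was set against all other genes with Fisher's exact test, two-sided, adjusted over the lists. Variation of each detected gene was tested with limma as its variance, with 7 residual degrees of freedom, against the trend of variance with level over all genes. This asks whether a gene varies more than is usual for its level. It does not ask whether a gene varies beyond technical noise, for which there is no replicate here.

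For a list or a chromosome, each detected member was centred on its mean over the tumours, the members were averaged in each tumour, and the SD of these averages over the 8 tumours was compared with 10000 random lists of as many detected genes matched on level in 10 bins. This permutation test is one-sided, adjusted over the lists or chromosomes with the Benjamini-Hochberg method, and its smallest p is 0.0001. Lists with fewer than 4 detected members were not tested. For chromosomes, each alternative used 1000 random lists. Of 16 planned relations over the tumours, 14 were computed with Pearson's r and Spearman's rho by exact permutation of the 40320 pairings, two-sided, with Benjamini-Hochberg adjustment over the family. The relation of Trp53 with its targets and that of macrophage with T cell genes could not be computed. Each r was computed again without the 2 tumours farthest from the median of the first measure, and genes shared by 2 lists were left out of the second. The tumours were also compared by Pearson's r over detected genes and by principal components. Computations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

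The genes named in the text are those fixed in advance, the 3 detected members with the largest SD of each list past the threshold, and the 20 genes with the largest SD among those past the variance test. As no gene passed that test, the 20 detected genes with the largest SD were named instead, and this choice was made after seeing the data. Any other gene named was chosen after its values were seen. The lists cover adrenergic transcription factors, catecholamine and secretory granule genes, neuronal genes, neuroblastoma oncogenes and receptors, mesenchymal-type neuroblastoma genes, neural crest progenitors, Schwann cells and glia, melanocytes, skeletal muscle, cartilage and bone, adipocytes, keratinocytes, fibroblasts and pericytes, endothelium, macrophages, T cells, NK cells, B cells, red blood cells, neutrophils, interferon response, MHC class I antigen presentation, cell cycle, ribosome biogenesis and Myc targets, p53 targets, hypoxia and glycolysis, immediate early and heat shock genes, and sex chromosome markers. The grouping, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise.

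Each result was computed again with the mean of all probe sets of a gene, with arrays centred and quantile normalized again, and without each tumour in turn. Further alternatives were 2 lower background levels and presence on every array, no filter on dim genes, a prior without the robust option and a minimum SD of 1, all list members, the median of members, members scaled to unit SD, and relations after a linear fit on the mean of the fibroblast, endothelial and macrophage lists. Added after seeing the data were a minimum SD set by receptor genes and the removal of tumours 4 and 6 together.

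The steps were tested on simulated data with known answers. For detection over 22180 genes, 94.8% of genes set 0.5 above background were called, 99.1% of those set 1 above, 1.61% of those at background and 0.0% of those set 0.5 below (a true offset of -0.5). In this simulation the background was a single level without spread between probe sets. On the real arrays a 95th percentile leaves some receptor probe sets above it by definition. The 1.61% is therefore no rate of false detection for the tumours, least of all for genes close to background. For variation, with the same SD for all genes, the test called 49.0% of genes with 2 times and 95.0% with 4 times the SD of the others, and 0.0182% of the others. With SDs scattered as in the tumours it called 0.0% of either. Of random lists of 10 genes given a shared shift with an SD of 0.3, 95.0% were called at p under 0.05, and 16.0% with an SD of 0.1, against 4.0% with no shift. For lists of 25 genes these shares were 100.0%, 73.0% and 6.0%, and for lists of 500 genes, about the size of a chromosome, 100.0%, 100.0% and 5.0%. The shares rest on 100 lists drawn per setting, and on 20 for lists of 500 genes. Apart from the shared shift, each simulated gene was drawn independently, whereas genes of the tumours can vary together. The shares with no shift are therefore no rate of false calls for the real lists and chromosomes.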

Results

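Gene expression was measured on 8 arrays, each holding the RNA of 1 primary subcutaneous tumour. The tumours grew from mouse neural crest cells, the embryonic cells from which sympathetic neurons, adrenal chromaffin cells, glia and pigment cells arise. The cells had been given N-Myc, the MYC family transcription factor amplified in high-risk human neuroblastoma, and were a mixture of p53 heterozygous and p53 null cells. About 10000 cells were injected per mouse 48 hours after infection, and the tumours were taken after about 50 days. The hosts were nude or C57Bl/6 mice, and the labels do not say which tumour grew in which host or which cells it came from. All 8 tumours carry the same label, so they form 1 group (n = 8), and no normal tissue, untransduced cells or other tumour type was analysed here. The labels do not state that each tumour came from a separate animal or a separate culture, so the limma detection tests and the relations cover only these samples. Fisher's exact test and the random lists take genes as units, which are not independent replicates. Their p-values set genes against other genes and are no measure of the spread between tumours. Array medians lay between 5.63 and 5.75 on the log2 scale. The background, set on each array by the probe sets of odorant, pheromone and bitter taste receptor genes, lay between 5.45 and 5.66, and 13062 to 13596 genes per array were above it. The number of arrays limits the precision of the values below.

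The series title names the question, whether N-Myc in neural crest cells gives neuroblastoma, and the first comparison sets each gene against the array background to show which cell type programmes the tumours expressed. Sympathoadrenal genes were above background. Isl1 reached 11.32 ± 0.46 (mean ± SD of log2 levels, n = 8) and Hand2 10.57 ± 0.35, both transcription factors of sympathetic neuron development, and Gata3, which acts in the same programme, reached 9.22 ± 0.97. Tyrosine hydroxylase (Th), the first enzyme of catecholamine synthesis, was at 10.05 ± 0.92, dopamine beta-hydroxylase (Dbh), which makes noradrenaline, at 10.15 ± 1.88, and the secretory granule protein genes Chga and Chgb at 10.74 ± 0.38 and 9.66 ± 1.37. The neuronal genes Stmn2 (12.56 ± 0.24), Tubb3 (12.07 ± 0.18), a neuronal beta-tubulin, and Syp (10.11 ± 0.19), a synaptic vesicle protein, were above background on all 8 arrays.

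By list, 26 of 26 measured neuronal genes, 16 of 17 catecholamine and secretory granule genes and 11 of 12 adrenergic transcription factors were above background. The exceptions were Pnmt (5.05 ± 0.23), which converts noradrenaline to adrenaline, and Hand1 (5.63 ± 0.27). The neuronal list held more detected genes than the array as a whole (Fisher's exact test, two-sided, adjusted p = 1.84e-05), as did the catecholamine list (adjusted p = 0.00955), while the adrenergic factors missed the threshold (adjusted p = 0.0542). Of the neuroblastoma oncogenes and receptors, 20 of 22 were detected (Fisher's exact test, adjusted p = 0.00627). Ret and Alk, receptor tyrosine kinases of sympathetic neuroblasts, were at 8.78 ± 0.78 and 8.34 ± 0.61. Mycn was at 6.65 ± 0.34, which is 1.06 above background, and Myc at 6.79 ± 0.32. Whether the Mycn probe set reads the introduced gene is not given in the sources used here. The cell cycle list was detected in full (24 of 24, Fisher's exact test, adjusted p = 3.16e-05), with Mki67 at 10.92 ± 0.20. So was the ribosome biogenesis and Myc target list (18 of 18, Fisher's exact test, adjusted p = 0.000462). The p53 target Cdkn1a, a cyclin-dependent kinase inhibitor, reached 9.55 ± 0.62, Mdm2, which encodes the ubiquitin ligase for p53, reached 7.98 ± 0.11, and 16 of 20 p53 target genes were detected (Fisher's exact test, adjusted p = 0.0741). Cdkn2a, a tumour suppressor locus, was at 6.70 ± 0.58.

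Pigment cell, cartilage and bone genes were mostly at background. Only 2 of 11 melanocyte genes were detected, fewer than on the array as a whole (Fisher's exact test, adjusted p = 0.0483): Kit (8.25 ± 0.78) and Mitf (5.89 ± 0.24), the latter close to background. Of cartilage and bone genes, 2 of 10 were detected, and of Schwann cell and glia genes 6 of 10 (Fisher's exact test, adjusted p = 0.0646 and 1.0). The mesenchymal-type neuroblastoma list had 14 of 18 genes detected (Fisher's exact test, adjusted p = 0.142), with Prrx1 and Snai2 at 6.81 ± 0.41 and 6.81 ± 0.32 and vimentin (Vim) at 12.23 ± 0.25. Fibroblast, endothelial and macrophage genes were detected in the same samples. Here and in the relations below, the arrays therefore do not show whether tumour cells or host cells made the mesenchymal-type genes. The neural crest progenitor list had 11 of 17 genes detected (Fisher's exact test, adjusted p = 0.704). Within it Sox10, a crest and glial transcription factor, averaged 6.44 ± 1.12 and passed the detection test only narrowly (limma, adjusted p = 0.0373). That call was lost without tumour 4 (6.17, limma, adjusted p = 0.0811), without tumour 6 (6.21, adjusted p = 0.0916), without tumour 7 (6.46, adjusted p = 0.0605) or without tumour 8 (6.49, adjusted p = 0.0546).

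Genes of other cell types were detected unevenly. Of macrophage genes 14 of 17 were detected, with Csf1r, a macrophage growth factor receptor, at 7.36 ± 0.38. Endothelial genes followed with 12 of 14 (Pecam1 at 7.85 ± 0.38) and fibroblast and pericyte genes with 13 of 15 (Col1a1 at 9.86 ± 0.56). These shares missed the threshold (Fisher's exact test, adjusted p = 0.0741, 0.0717 and 0.0717). T cell genes were largely below background, with 1 of 11 detected (Fisher's exact test, adjusted p = 0.0076), namely Cd4 at 5.86 ± 0.31, while Cd3e, part of the T cell receptor complex, was at 5.01 ± 0.26. Detected were 2 of 9 NK cell genes, 1 of 7 B cell genes, 3 of 8 neutrophil genes, 0 of 2 red blood cell genes, 3 of 9 adipocyte genes and 2 of 9 keratinocyte genes. None of these shares passed (Fisher's exact test, adjusted p of 0.0741 or above). Of skeletal muscle genes 9 of 14 were detected (Fisher's exact test, adjusted p = 0.849), but Myod1, which starts muscle differentiation, was at background (5.45 ± 0.26). The remaining lists had 8 of 12 (interferon response), 5 of 9 (MHC class I antigen presentation), 11 of 12 (hypoxia and glycolysis), 9 of 11 (immediate early and heat shock) and 0 of 4 genes detected (sex chromosome markers, which are high in some tumours only). Over all 22180 genes, limma called 12706 (57.3%) above background. The background level sets this count, which was 20164 against the median of the receptor probe sets. Of the 27 measured genes named in advance, 25 were detected, both over all genes and adjusted over the list alone, and of the 28 lists 26 had the same count adjusted over the list alone.

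**Figure D1:**
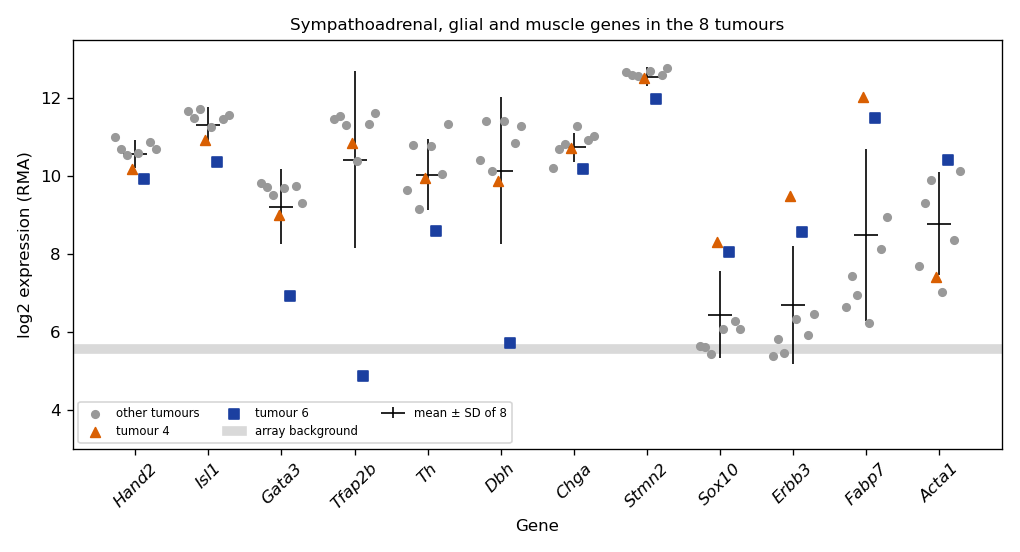
Log2 expression (vertical axis) of 12 genes (horizontal axis) in each of the 8 tumours, with tumour 4 as triangles, tumour 6 as squares, the other tumours as circles, black bars for the mean ± SD and a grey band for the range of array background. In tumour 6, Tfap2b (4.88) lay below the background and Dbh (5.72) just above it, while Fabp7 reached 12.03 and 11.51 in tumours 4 and 6.

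The tumours resembled each other across genes, and the pair that differed most was tumours 6 and 8. Over the 12706 detected genes, Pearson's r between pairs of tumours ran from 0.904 (tumours 6 and 8) to 0.974 (tumours 2 and 7), with a median of 0.947. These correlations are across genes, which are not independent replicates. Tumours 1, 2 and 7 were close to each other (r of 0.972 for tumours 1 and 2, and 0.972 for 1 and 7). The first principal component held 34.5% of the variance, with its largest loadings on tumour 6 (0.695) and tumour 4 (0.424).

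The second comparison asks which genes differed most between the tumours. Tfap2b, a transcription factor of sympathetic neuron development, had the largest SD of all detected genes (2.28). It was at 4.88 in tumour 6 and at 11.22 ± 0.44 (SD, n = 7) in the others. Dbh (SD 1.88) was at 5.72 in tumour 6 and at 10.78 ± 0.64 (SD, n = 7) in the others, whereas Eya2, a transcriptional coactivator and phosphatase, was at 11.32 in tumour 6 and 6.69 ± 0.49 (SD, n = 7) elsewhere. Fabp7, a fatty acid binding protein of glial progenitors (SD 2.20), was at 12.03 in tumour 4 and 11.51 in tumour 6, against 6.24 to 8.96 in the other 6. Npy, a neuropeptide of sympathetic neurons (SD 1.89), ranged from 6.41 in tumour 6 to 11.60 in tumour 2, and Vip, another neuropeptide (SD 1.84), from 6.24 in tumour 4 to 11.85 in tumour 7.

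Other genes with large SDs were Ddc, which makes dopamine (1.69, lowest in tumour 6 and highest in tumour 2), Gad2, which makes GABA (1.72, lowest in tumour 6 and highest in tumour 8), and Htr3a, a serotonin receptor channel (1.68, lowest in tumour 5 and highest in tumour 4). Crabp1, a retinoic acid binding protein, was at 12.05 in tumour 6 and 6.97 in tumour 2 (SD 1.67). Dlx5, a homeobox gene, was at 9.85 in tumour 5 and 4.995 in tumour 8 (SD 1.68). Mmd2 was at 10.03 in tumour 4 and 9.72 in tumour 6, with 5.93 to 6.63 elsewhere, and St18 was at 9.27 and 9.43 in these tumours (SD 1.58). Car3, a carbonic anhydrase abundant in muscle and fat, ran from 5.36 in tumour 4 to 9.71 in tumour 8 (SD 1.79), and was below the detection threshold when the probe sets of the gene were averaged (6.32, limma, adjusted p = 0.171). The remaining genes of the 20 with the largest SD were 2900092D14Rik (2.24), Dgkk (1.87), Chrdl1 (1.72), Pou3f3 (1.70), Fam160a1 (1.59) and 6330403K07Rik (1.58). Of these, 2900092D14Rik lost its detection call without tumour 1, 2, 4, 7 or 8 (6.82, 6.92, 7.27, 6.92 and 7.05, with limma adjusted p of 0.117, 0.109, 0.0648, 0.113 and 0.103). Pou3f3 lost it without tumour 1, 2, 7 or 8 (6.74, 6.87, 6.81 and 6.87, with limma adjusted p of 0.0627, 0.0568, 0.0627 and 0.0626).

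No detected gene passed limma's test of its variance against the trend of all genes (lowest adjusted p = 0.701), and 796 (6.26%) had an unadjusted p under 0.05, so these 20 genes were chosen after their values were seen. Adjusted over the list alone, 5 of the 25 detected genes named in advance and 21 genes over 7 of the 28 lists passed. In simulated data whose SDs scattered as widely between genes as in the tumours, the test called 0% of genes with a 4 times larger SD, so the count of 0 is a property of the test as much as of the tumours. By size alone, 154 detected genes had an SD of at least 1 and 1850 an SD above the 99th percentile of receptor genes (0.41). The median SD was 0.23 for detected genes and 0.16 for receptor genes.

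**Figure D2:**
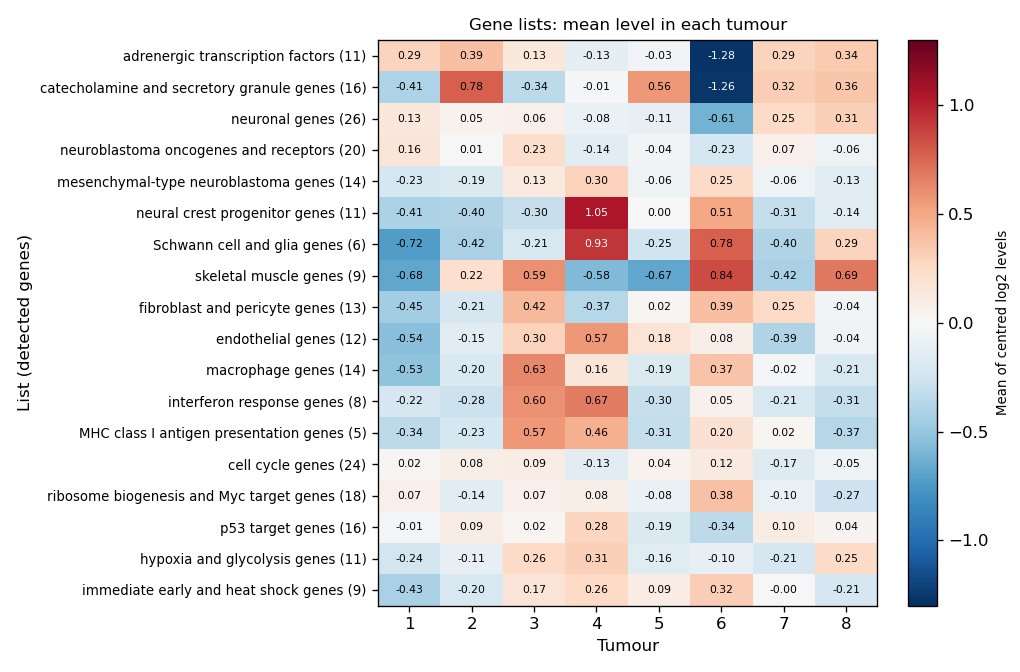
Mean of the centred log2 levels of each list's detected genes (rows, with the number of genes) in each of the 8 tumours (columns), with red above and blue below the list's mean over the tumours. The lowest values are those of tumour 6 for adrenergic transcription factors (-1.28) and catecholamine genes (-1.26), and the highest that of tumour 4 for neural crest progenitor genes (1.05).

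The third comparison asks whether the genes of a list differed between tumours together. The sympathoadrenal lists had their lowest means in tumour 6. The mean of the 11 detected adrenergic transcription factors was -1.28 there and between -0.13 and 0.39 in the other tumours. Of the 11, 7 had their lowest level in tumour 6 and 2 their highest, Insm1 (8.80) and Dach1 (10.46). Tfap2b, Gata2 (5.45 in tumour 6, 8.22 ± 1.43 over all 8) and Tbx2 (6.24 in tumour 6, 8.63 ± 1.03 over all 8) varied most. The 16 catecholamine and granule genes were at -1.26 in tumour 6 and highest in tumour 2 (0.78) and tumour 5 (0.56), with 11 of 16 lowest in tumour 6, and Dbh, Npy and Ddc varied most. The 26 neuronal genes were at -0.61 in tumour 6, with 17 of 26 lowest there. Prph, a peripheral neuron filament protein, was highest in tumour 7 (9.94), while Nrcam, an adhesion molecule, was lowest in tumour 6 (8.71), and Cntn1 was lowest in tumour 5 (7.83). The SD over the tumours was 0.55 for the adrenergic factors, 0.66 for the catecholamine genes and 0.29 for the neuronal genes, each beyond all 10000 random lists matched on level (one-sided permutation p = 0.0001, the smallest these lists can give, adjusted p = 0.0002). Without tumour 6 the SD was 0.20 for the adrenergic factors (adjusted p = 0.00735) and 0.16 for the neuronal genes (adjusted p = 0.000225), and both calls held.

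The lists of crest progenitor and glia genes had their highest means in tumours 4 and 6. The 11 neural crest progenitor genes were at 1.05 in tumour 4 and 0.51 in tumour 6, and at 0.00 or below in the other 6, with 8 of the 11 highest in tumour 4 and 1 in tumour 6. Erbb3, a neuregulin receptor of glial precursors, was at 9.50 in tumour 4 and 8.58 in tumour 6, against 5.40 to 6.48 elsewhere. Sox10 was at 8.32 and 8.05 in these tumours, against 5.43 to 6.30 elsewhere. Ednrb, an endothelin receptor of migrating crest cells, was at 8.63 in tumour 4 and at 7.34, 7.11 and 6.77 in tumours 3, 5 and 6. The 6 Schwann cell and glia genes were at 0.93 in tumour 4 and 0.78 in tumour 6. Fabp7 and Pmp22, a myelin protein gene, were highest in tumour 4 (12.03 and 8.66), and Pou3f1 in tumour 6 (7.90). The SDs were 0.52 and 0.60 (adjusted p = 0.0002 for both lists). Without tumour 4 the SD of the progenitor list was 0.20 (adjusted p = 0.036). Erbb3 lost its detection call without tumour 4, 5, 6, 7 or 8, at 6.29, 6.74, 6.42, 6.80 and 6.72 (limma, adjusted p = 0.0893, 0.0597, 0.121, 0.0537 and 0.0742). The 14 mesenchymal-type genes also varied (SD 0.20, adjusted p = 0.0135), with tumour 4 at 0.30 and tumour 6 at 0.25. Notch1 was highest in tumour 4 (8.22), Notch2 in tumour 6 (7.50), and Twist1 in tumours 3 and 1 (7.89 and 7.88). The mesenchymal call was lost when tumours 4 and 6 were both left out (SD 0.13, adjusted p = 0.134).

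Genes of skeletal muscle, macrophages, endothelium and fibroblasts differed between tumours, and all 4 lists were lowest in tumour 1. The 9 skeletal muscle genes were at 0.84 in tumour 6, 0.69 in tumour 8 and 0.59 in tumour 3, and at -0.68, -0.67 and -0.58 in tumours 1, 5 and 4 (SD 0.66, adjusted p = 0.0002). Acta1, skeletal muscle actin, ranged from 7.03 in tumour 5 to 10.43 in tumour 6, Tnnt3, a troponin, from 6.44 to 9.44, and Ckm, muscle creatine kinase, from 5.91 to 8.75. The 14 macrophage genes were highest in tumours 3 and 6 (0.63 and 0.37) and lowest in tumour 1 (-0.53), with 12 of 14 highest in tumour 3 (SD 0.37, adjusted p = 0.0002). Ctss, a lysosomal protease, Ms4a7 and Adgre1, the F4/80 antigen, were at 9.46, 9.38 and 8.04 in tumour 3. The 12 endothelial genes were highest in tumour 4 (0.57) and lowest in tumour 1 (-0.54; SD 0.36, adjusted p = 0.0002), with Emcn, Cdh5 and Tie1 at 9.30, 9.44 and 7.34 in tumour 4. The 13 fibroblast and pericyte genes were highest in tumours 3 and 6 (0.42 and 0.39) and lowest in tumour 1 (-0.45; SD 0.33, adjusted p = 0.0002). Postn, Dcn and Mfap5, matrix protein genes, varied most, with Postn highest in tumour 7 (10.65) and the other 2 in tumour 3 (9.01 and 8.26).

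The lists of interferon and antigen presentation genes had their highest means in tumours 3 and 4. The 8 interferon response genes were at 0.67 in tumour 4 and 0.60 in tumour 3 and at or below 0.05 elsewhere (SD 0.41, adjusted p = 0.00054). Oasl2 was at 8.04 and 7.97 in tumours 4 and 3, Rtp4 at 7.44 and 7.22, and Bst2 at 7.75 and 7.11, with 7.16 in tumour 6. The 5 MHC class I genes were at 0.57 in tumour 3 and 0.46 in tumour 4 (SD 0.37, adjusted p = 0.00996). In tumours 3, 4, 6, 1 and 8 the MHC class I list was at 0.57, 0.46, 0.20, -0.34 and -0.37 and the macrophage list at 0.63, 0.16, 0.37, -0.53 and -0.21. In tumours 3, 4 and 6, H2-K1, a class I heavy chain, was at 9.18, 8.99 and 8.92, B2m, its light chain, at 12.58, 12.46 and 12.50, and Tap1, a peptide transporter, at 7.52, 7.38 and 6.86. Rtp4 lost its detection call without tumour 3 (6.02, limma, adjusted p = 0.08), tumour 4 (5.99, adjusted p = 0.0805) or tumour 6 (6.20, adjusted p = 0.0593).

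Growth and stress genes also differed between tumours. The 18 ribosome biogenesis and Myc target genes were highest in tumour 6 (0.38) and lowest in tumour 8 (-0.27), with 15 of 18 highest in tumour 6 (SD 0.20, adjusted p = 0.00164). Srm, a polyamine synthesis enzyme, was at 12.12 there, Cad, which starts pyrimidine synthesis, at 9.80 and Dkc1 at 10.39. The 24 cell cycle genes had an SD of 0.11 (adjusted p = 0.0303), with tumour 7 at -0.17 and tumour 6 at 0.12. Mcm5, Bub1b and Aurka varied most, with SDs of 0.31, 0.29 and 0.28. The cell cycle call was lost without tumour 4 (SD 0.10, adjusted p = 0.0599), without tumour 7 (0.090, adjusted p = 0.0662) and with arrays normalized again (0.091, adjusted p = 0.0652). The 16 p53 target genes were highest in tumour 4 (0.28) and lowest in tumour 6 (-0.34; SD 0.19, adjusted p = 0.00705), where Cdkn1a (8.36), Plk2 (6.29) and Trp53inp1 (6.00) were lowest. The p53 target call was lost with the median of members (SD 0.11, adjusted p = 0.0865) and without tumours 4 and 6 (0.11, adjusted p = 0.179).

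The 20 neuroblastoma oncogenes and receptors were highest in tumour 3 (0.23) and lowest in tumour 6 (-0.23; SD 0.15, adjusted p = 0.0159). Ntrk3, a neurotrophin receptor, was at 6.33 in tumour 6 with a mean ± SD of 8.5 ± 1.07 over all 8, and Ntrk2, a related receptor, was highest in tumour 6 (7.84). This call was lost without tumour 3 (SD 0.13, adjusted p = 0.0508), with members scaled to unit SD (0.31, adjusted p = 0.173), and without tumours 4 and 6 (0.12, adjusted p = 0.0706). The 11 hypoxia and glycolysis genes were highest in tumours 4, 3 and 8 (0.31, 0.26 and 0.25; SD 0.23, adjusted p = 0.00996). Egln3, an oxygen sensor, was highest in tumour 3 (8.41), and Slc2a1, a glucose transporter, and Ndrg1 in tumour 8 (9.13 and 9.66). The 9 immediate early and heat shock genes were highest in tumour 6 (0.32) and lowest in tumour 1 (-0.43; SD 0.26, adjusted p = 0.00996), with Hspa1b at 5.30, Ier2 at 5.90 and Atf3 at 6.98 in tumour 1, and Atf3 at 6.85 in tumour 8. All 18 lists with at least 4 detected genes passed the threshold. The random lists were matched on level but not on function, whereas each of these lists was made of genes of 1 cell type or programme. A pass therefore shows only that the members varied together more than unrelated genes, and it does not single out any list. The other 10 had fewer detected genes and were not tested.

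**Figure D3:**
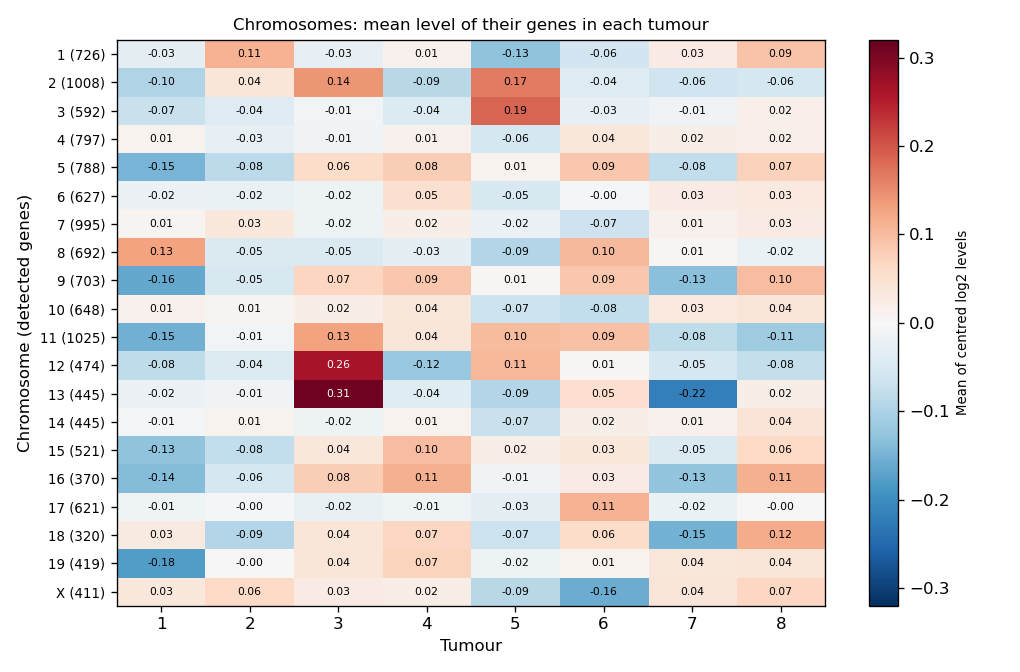
Mean of the centred log2 levels of each chromosome's detected genes (rows, with the number of genes) in each of the 8 tumours (columns), with red above and blue below the chromosome's mean over the tumours. The largest shifts are those of chromosomes 13 and 12 in tumour 3 (0.31 and 0.26) and of chromosome 13 in tumour 7 (-0.22).

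The fourth comparison asks whether the genes of a chromosome differed between tumours together, as they would where copy number differs. No DNA was measured. The 445 detected genes of chromosome 13 were on average 0.31 higher in tumour 3 than over all tumours (24.1%), and in tumour 7 their mean shift was -0.22 (-14.0%). The 474 genes of chromosome 12, which carries Mycn, were 0.26 higher in tumour 3, the tumour with the highest Mycn level (7.11). However, tumour 8 had Mycn at 6.99 with a chromosome 12 shift of -0.08, and tumour 5 had Mycn at 6.73 with a shift of 0.11. Whether Mycn follows chromosome 12 over the tumours was not tested. Chromosome 3 was 0.19 higher in tumour 5, and chromosome 2 was 0.17 higher in tumour 5 and 0.14 higher in tumour 3. In tumour 1, chromosomes 19, 9, 11 and 5 had shifts of -0.18, -0.16, -0.15 and -0.15, and in tumour 6 the X chromosome had a shift of -0.16.

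Of 20 chromosomes tested, 16 varied more than random gene lists of the same size and level (one-sided permutation test, adjusted p = 0.000143 for 14 of them, from a p of 0.0001, the smallest 10000 random lists can give, 0.0125 for chromosome 10 and 0.0226 for chromosome 17). Chromosomes 4, 6, 7 and 14 did not pass (adjusted p = 0.82, 0.648, 0.648 and 0.648). The SD was 0.15 for chromosome 13 and 0.13 for chromosome 12, and without tumour 3 it was 0.089 and 0.075 (adjusted p = 0.00125 for both). The X chromosome had an SD of 0.081, and 0.053 without tumour 6 (adjusted p = 0.0285). Several calls rested on 1 tumour. Chromosome 3 had an SD of 0.080, and 0.029 without tumour 5 (adjusted p = 1.0). For chromosome 19 it was 0.077, and 0.030 without tumour 1 (adjusted p = 0.619). For chromosome 17 it was 0.046, and 0.011 without tumour 6 (adjusted p = 1.0), and 0.055 with arrays normalized again (adjusted p = 0.213). Chromosome 10 (SD 0.047) lost its call without tumour 5 (0.040, adjusted p = 0.337), without tumour 6 (0.037, adjusted p = 0.47) and with arrays normalized again (0.051, adjusted p = 0.249). Chromosome 7 passed without tumour 1 (0.035, adjusted p = 0.0425), with the median of members (0.033, adjusted p = 0.0447) and with members scaled to unit SD (0.14, adjusted p = 0.00705).

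The last comparison asks which programmes moved together over the 8 tumours, in a family of 14 relations. Adrenergic transcription factors and neuronal genes were high and low in the same tumours. Pearson's r was 0.944 (exact permutation p = 0.00255, adjusted p = 0.0179) and Spearman's rho 0.714 (exact permutation p = 0.0576, adjusted p = 0.161). Without tumours 4 and 6, the farthest from the median, r was 0.70 (exact permutation, adjusted p = 0.439). With 7 tumours the call was also lost without tumour 6 (r = 0.775, exact permutation, adjusted p = 0.165) and without tumour 5 (r = 0.951, exact permutation, adjusted p = 0.0625). Interferon response and MHC class I genes also went together, with r = 0.938 (exact permutation p = 0.00146, adjusted p = 0.0179) and rho = 0.905 (exact permutation p = 0.00456, adjusted p = 0.05), and r was 0.866 without tumours 3 and 4, the farthest from the median. With 6 tumours this call was lost without tumours 4 and 6 (r = 0.956, exact permutation, adjusted p = 0.0681).

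The other 12 relations did not pass. Macrophage genes and mesenchymal-type genes had r = 0.808 (exact permutation p = 0.0148, adjusted p = 0.0676) and rho = 0.857 (exact permutation p = 0.0107, adjusted p = 0.05), with r of 0.857 without tumours 3 and 6. This relation passed without tumour 3 (r = 0.90, exact permutation, adjusted p = 0.0222), without tumour 4 (r = 0.898, adjusted p = 0.0444), and with the mean of all probe sets (r = 0.864, adjusted p = 0.0226). Adrenergic factors and mesenchymal-type genes had r = -0.704 (exact permutation p = 0.0193, adjusted p = 0.0676) and rho = -0.881 (exact permutation p = 0.00724, adjusted p = 0.05), with r of -0.562 without tumours 4 and 6. Both lists were above 0 in tumour 3 (0.13 for each) and below 0 in tumour 5 (-0.03 and -0.06). This relation passed with the mean of all probe sets (r = -0.709, exact permutation, adjusted p = 0.0455), with all members on the array (r = -0.76, adjusted p = 0.00868) and with members scaled to unit SD (r = -0.819, adjusted p = 0.0211). Adrenergic factors and catecholamine genes had r = 0.773 (exact permutation p = 0.0402, adjusted p = 0.107) and rho = 0.548 (exact permutation p = 0.171, adjusted p = 0.378), and r of 0.102 without tumours 4 and 6.

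Mycn had r = 0.772 with adrenergic factors (exact permutation p = 0.0459, adjusted p = 0.107; rho = 0.381, p = 0.36) and r = -0.673 with ribosome biogenesis and Myc target genes (exact permutation p = 0.0691, adjusted p = 0.121; rho = -0.50, p = 0.216). Without tumours 3 and 6 these were 0.349 and -0.67. The first passed after a linear fit on the stroma lists (r = 0.876, exact permutation, adjusted p = 0.0292) and the second without tumour 3 (r = -0.897, exact permutation, adjusted p = 0.0389). The p53 targets had r = -0.674 with cell cycle genes (exact permutation p = 0.0632, adjusted p = 0.121; rho = -0.714, p = 0.0576), and r of -0.341 without tumours 4 and 6. The other 6 relations, of Mycn with mesenchymal-type, cell cycle and macrophage genes and with Myc, of fibroblast with endothelial genes, and of hypoxia with cell cycle genes, had r between -0.409 and 0.325 (exact permutation p of 0.324 or above) and rho between -0.31 and 0.50 (exact permutation p of 0.216 or above). Without the 2 tumours farthest from the median their r lay between -0.529 and 0.584.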

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

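The tests of explanations for tumour 6 and the test of host cells for the chromosomes were chosen after the results were seen, those of host stromal cells and of the spread in tumour 6 after the comparison of its catecholamine and neuronal medians. The labels give 1 group, so no biological explanation from the design was tested. Each value for a single tumour was set against the other 7 by its gap to the nearest tumour divided by the range of all 8. Of 130 genes, lists and chromosomes examined, 15 had a tumour past Dixon's 95% limit, and 11 of the 15 were in tumour 6. Chance gives about 1 in 20 for values not chosen by their spread, but many of these genes were chosen for a large SD, and the lists contain some of them, so that share is no measure of chance here.

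In tumour 6, the adrenergic transcription factor list (-1.28, gap 0.687 of the range) and the neuronal list (-0.61, gap 0.543) were lowest, as were Tfap2b (4.88, gap 0.817), Dbh (5.72, gap 0.727), Gata3 (6.93, gap 0.717), Tbx2 (6.24, gap 0.685) and Stmn2 (11.99, gap 0.68). A loss of whole chromosomes that carry the catecholamine genes does not account for this, as the lowest chromosome shift among them in tumour 6 was -0.158. The fibroblast (0.39), macrophage (0.37) and skeletal muscle lists (0.84) were high in tumour 6 and the endothelial list less so (0.08). The cell cycle list's median change in tumour 6 against the mean of the other 7 was 0.135, while the neuronal list's was -0.704. This difference had a two-sided permutation p of 2e-05, the smallest 100000 resamples can give, across genes, which are not independent replicates. It argues against more host stromal cells as the whole cause only if the tumour cells cycled as in the other tumours. That was not measured, and the ribosome biogenesis and Myc target list was highest in tumour 6 (0.38). More cells of other types, host cells as a part of them, stay open. The catecholamine list's median change, -0.822, was near the neuronal list's (two-sided permutation p = 0.65 for the difference, which does not show that they were equal). Over the 27 adrenergic and catecholamine genes the changes had an SD of 1.698 in tumour 6 and at most 0.972 in another tumour. Tfap2b was at -6.34 and Dbh at -5.05, but Sox11 at 0.04 and Dach1 at 0.80. Added cells that make none of these genes would lower all of them alike. The spread argues against such cells as the whole cause. It cannot decide on added cells that make some of these genes, since the arrays do not show which cells made them. The spread was also examined only after Tfap2b and Dbh had stood out in tumour 6. In tumour 6, Tfap2b (4.88), Gata2 (5.45) and Slc18a1 (5.14) lay below the array background of 5.54. Their changes, and the SD that includes them, are therefore not exact. A shift to cholinergic genes was not decided. Chat, Slc18a3 and Slc5a7, chosen after their values were seen, were on average 1.59 above their mean in tumour 6. Chat and Slc5a7 were not detected over the tumours and were above background on 4 of 8 arrays each. The mean of the 3 genes had r = -0.707 with the catecholamine list (exact permutation p = 0.0505, rho = -0.548, exact permutation p = 0.171). All 3 were highest in tumour 6, where that list was lowest, so these p-values do not test such a shift. Without tumour 6 r was -0.263 (exact permutation p = 0.557) and without tumours 6 and 8, the farthest from the median, it was -0.196, so the relation rests on tumour 6, and such a shift may concern that tumour alone.

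The other genes that stood out in tumour 6 were higher there. Eya2 was at 11.32 (gap 0.729), Cad at 9.80 (gap 0.589) and Cdkn2a at 8.01 (gap 0.575), against 6.51 ± 0.25 (SD, n = 7) for Cdkn2a in the others. Snai2 was highest in tumour 3 (7.48, gap 0.53) and Notch1 in tumour 4 (8.22, gap 0.566).

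Among chromosomes, chromosome 3 was highest in tumour 5 (0.19, gap 0.661 of the range), chromosome 17 highest in tumour 6 (0.11, gap 0.795) and chromosome 19 lowest in tumour 1 (-0.18, gap 0.65). A few strongly varying genes do not account for the chromosome shifts, since 16 of the 16 chromosomes that passed kept their call with the median of their genes. After a linear fit of each gene on the mean of the stroma lists, 16 of 16 kept an SD above the 95th percentile that random lists had before the fit. The margin was small for chromosomes 17 (0.0444 against 0.0438) and 10 (0.0455 against 0.0425). The fit lowered the SD from 0.11 to 0.058 for chromosome 11, from 0.092 to 0.056 for chromosome 5, from 0.105 to 0.072 for chromosome 9, and from 0.077 to 0.053 for chromosomes 15 and 19. A shared rise of these lists thus does not account for all shifts. Host cells in general stay open, because the fit removes only that mean. The fibroblast, endothelial and macrophage lists differed, as in tumour 4 (-0.37, 0.57 and 0.16), and muscle genes were not in the fit. A change along the whole chromosome is a candidate explanation that stays open and was not decided: the 2 parts of a chromosome, divided at its middle gene, had a median r of 0.904 over the tumours for the 16 chromosomes, but these were chosen because their means varied, and chromosome 14, which did not pass, had r = 0.91, also above 0.85, the 95th percentile of r between parts of different chromosomes. Of the 16, 6 lay below that percentile, with r of 0.593 for chromosome 17, 0.699 for 19, 0.754 for 18, 0.785 for 12 (high in tumour 3), 0.815 for 15 and 0.839 for 1.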

How the results depend on the processing

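Of 1883 values under alternatives for 150 results, 1801 were labelled the same, and 118 results were so labelled under every alternative run. For a gene, list, chromosome or relation, the label means the same side of the threshold and, for relations, the same sign. Counts were labelled the same within a fixed fold tolerance, as with 17614 against 12706 detected genes. Most of the values are detection calls of the 92 genes named by rule, so the total says little about the less certain results. The removal of tumours 4 and 6 together and the SD limit from receptor genes were chosen after seeing the data. No paired analysis was possible because the labels give a single group. The alternative without probe sets of particular suffixes was not run, since these probe sets carry plain numbers, and the chromosome test without genes past the variance test changes nothing, since none passed. Detected genes numbered 12083 to 17614 under the other alternatives and 20164 against the median of the receptor probe sets, a lower background by construction. The variance test gave 0 genes under each of its alternatives, while 154 genes had an SD of at least 1 and 1850 an SD above the receptor limit, which are other criteria. Lists past the threshold numbered 15 to 21 and chromosomes 14 to 17. The lowest correlation between tumours was 0.968 over all genes, which adds genes at background. Relations past the threshold numbered 2 as reported, 4 with the mean of all probe sets, 4 after the fit on the stroma lists, 0 without tumours 4 and 6 (fewer samples), and 1 (without tumour 5 or 6) to 4 (without tumour 3) when single tumours were left out. Relations that changed sign under an alternative were not past the threshold as first computed with all 8 tumours. Without tumours 4 and 6, Mycn had r = -0.28 with adrenergic factors, 0.686 with mesenchymal-type genes, 0.131 with cell cycle genes, 0.079 with ribosome biogenesis genes and 0.646 with macrophage genes, and hypoxia had 0.246 with cell cycle genes. When single tumours were left out, r ranged from -0.447 to 0.348 for Mycn with cell cycle genes, from -0.737 to 0.413 for Mycn with macrophage genes, from -0.264 to 0.633 for fibroblast with endothelial genes and from -0.536 to 0.166 for hypoxia with cell cycle genes. The cause was not tested. Fibroblast with endothelial genes gave -0.919 after the fit on the stroma lists (exact permutation, adjusted p = 0.0117), and is 1 of the 4 relations past the threshold there. The mean removed by that fit contains both lists, so this value cannot be read as a relation between them. Sox10, Erbb3, Rtp4, 2900092D14Rik and Pou3f3 are those among the named genes whose detection calls changed when tumours were left out, with means 0.58 to 1.61 above background and SDs of 0.74 to 2.24.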

Other observations

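The tests of muscle genes below were chosen after the results were seen, and the genes in this part outside the lists were chosen after their values were seen. Some glial, pigment cell and HoxA genes were high in tumour 4. Gfap, an astrocyte and glial filament protein, was at 10.71 in tumour 4 and at 5.05 to 5.93 in the others. Cdh19, a cadherin of Schwann cell precursors, was at 7.20 in tumour 4 and 6.24 in tumour 6, and at 4.29 or lower in the other 6. The pigment cell genes Dct and Pmel were at 8.01 and 6.76 in tumour 4, and at 5.52 or lower for Dct and 5.36 or lower for Pmel in the others. Of the other melanocyte genes, Tyr (3.91), Oca2 (4.94), Slc45a2 (5.26), Gpr143 (4.57) and Trpm1 (5.06) were below background in tumour 4, and Kit was highest in tumour 6 (9.64). The melanocyte list had too few detected genes to be tested. Several genes of the HoxA cluster, which set position along the body axis, were also highest in tumour 4: Hoxa5 was at 8.33 (5.25 or lower elsewhere), Hoxa6 at 9.35 (6.72 or lower), Hoxa7 at 7.79 (5.86 or lower) and Hoxa9 at 9.15 (5.47 or lower), while Hoxa2, Hoxa3, Hoxa10 and Hoxa13 were below background in all 8. Hoxd8 ran from 5.06 in tumour 6 and 5.16 in tumour 1 to 8.31 in tumour 3.

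All measured genes of the keratinocyte list but Dsg1a had their highest level in tumour 5. Krt14, a basal keratinocyte keratin, was at 9.13 there and at 5.29 or lower in the others, Krtdap at 8.68 (5.24 or lower) and Krt1 at 7.54 (5.40 or lower), and outside the list 2610528A11Rik was at 10.06 (6.67 or lower). Krt10 (7.68), Lor (6.84), Dsp (6.62), Ivl (5.85) and Trp63 (5.84) were also highest in tumour 5, the last 2 close to background. Dsg1a, also on the list, was at 5.52 in tumour 5, below background, and highest in tumour 8 (5.61). With 2 of 9 genes detected, the list was not tested.

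Sex-linked transcripts differed between tumours. Xist, made from the inactive X chromosome, was at 11.09, 10.08 and 9.64 in tumours 8, 3 and 4 and at 4.94 or lower in the other 5. The Y-linked genes Kdm5d and Uty were at 8.04 and 7.65 in tumour 1, 7.88 and 7.66 in tumour 2, 6.70 and 6.78 in tumour 4, 6.64 and 6.96 in tumour 5 and 6.64 and 6.38 in tumour 6, and below 5 in tumours 3, 7 and 8. Eif2s3y, also Y-linked, was at 7.25, 7.94 and 6.82 in tumours 4, 5 and 6, and at 4.599 and 4.702 in tumours 1 and 2, which had the highest Kdm5d. Tumour 4 had both Xist and Y-linked genes, and tumour 7 had neither (Xist 4.19, Kdm5d 4.74).

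The source of the muscle genes that differed between tumours was not decided. The 7 contractile genes Acta1, Ckm, Tnnt3, Mylpf, Tnni2, Tnnc2 and Myl1, chosen from the list after their values were seen, had a mean pairwise r of 0.907 over the 8 tumours, with averages of 1.27, 0.92 and 0.81 in tumours 6, 8 and 3 and -0.95 in tumour 4. Genes chosen in this way do not test whether they move together, and 2 fast adult myosins outside the list differed from them: Myh4 was at 8.96 in tumour 6 but 5.68 in tumour 3 and 4.89 in tumour 8, and Myh1 at 8.20 in tumour 3 but 5.02 in tumour 6. Adult muscle of the host and muscle-like tumour cells cannot be told apart as sources, because only 1 of 5 genes of early muscle, Myog (6.31 ± 0.16, n = 8), was above background on all arrays, and their mean had r = -0.168 with the contractile genes (exact permutation p = 0.674). No biological explanation from the design was tested.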
